A study of Mus musculus with 6 samples.

How the data were processed

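RNA was measured in 6 libraries of pooled fetal mouse hearts, 3 from sham-exposed and 3 from nano-TiO2-exposed dams, the input libraries of an m6A immunoprecipitation study. Per the labels' protocols, 14 dams aged 10 weeks entered the study, 3 µg of RNA was fragmented, and libraries were made with a low-input kit and sequenced on a NextSeq 2000. The group and number of each library came from its title.

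The estimated counts of reads per transcript were made by Salmon, per the file headers, and deposited without scaling. The TPM values beside them were computed by Salmon from estimated reads and effective length, per the file headers. The table of the whole series holds a signal per bin: reads in steps of about 25 bases along each gene, divided by the authors by 1 size factor per library, so that 100% of its values came out as whole reads within a tolerance of 0.001. The submitters' processing notes list HISAT2 2.2.1, Salmon 1.5.2, DESeq2 1.34.0 and the build GRCm39 without roles; the counting tool and strand setting of the table are not given in the sources used here. Gene symbols, transcript classes, lengths and GC content came from GENCODE M21, a GRCm38 annotation, so no coordinates are given. Of 116747 transcripts in each file, 115685 matched by ID, giving 35458 genes, and 1062 did not and were left out.

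Estimated reads were summed per gene and rounded to whole numbers. The main test was edgeR's quasi-likelihood test (robust) with group as the only term, TMM scaling and filterByExpr, which kept 13930 genes, at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes come from edgeR and those of lists from camera unless another tool is named. CPM values of genes use TMM scaling, and log2 CPM for the principal components used a prior count of 2. The biological coefficient of variation was 23.9%. With 3 libraries per group the estimated reads ranged from 12881945 to 22720009. Libraries of 1 group differed by more than sampling noise, so none was counted as a copy of another.

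Before the data were examined, 40 gene lists were fixed, and 39 had at least 3 tested members. They cover m6A writers, erasers and readers; antioxidant and NRF2 targets; xenobiotic response; mitochondrially encoded proteins, complex I and complexes II to V; mitochondrial ribosome and biogenesis; mitochondrial dynamics, mitophagy and import; fatty acid oxidation; glycolysis; hypoxia; sarcomere; calcium handling and conduction; hypertrophy; cardiac transcription factors; cell cycle; p53 targets; unfolded protein response; heat shock; immediate early, inflammation and interferon-stimulated genes; cytosolic ribosomal proteins; replication-dependent histones; chromatin modifiers; imprinted and IGF genes. The other lists hold erythroid, fibroblast, endothelial, epicardial, smooth muscle, macrophage, hepatocyte, lung, skeletal muscle, neural and platelet markers and sex-linked genes. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The estimated setting rests on the few residual degrees of freedom of 6 libraries, so failing it does not alone show correlated genes. The rule for named genes, also fixed before, took 6 anchors (Mettl3, Mettl14, Fto, Alkbh5, Ythdf2 and Gpx4), the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM, an ordinary symbol and non-overlapping groups, and up to 4 members with the smallest p of each list past camera and of 5 set lists. It gave 100 names and 90 different genes, some of which are not reported here. Genes shown as single values outside this rule (Afp, Alb, Sftpc, Slc25a37, globins and nuclear RNAs) were chosen after their values were seen.

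Bins of the series table with a mean of at least 10 (245114 of 5193362) were tested with limma on log2(value + 1) with the authors' scaling. The table was not planned with alternatives, so those tried on it were chosen after seeing the data.

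Alternatives fixed beforehand were RLE and upper-quartile factors, library totals only, DESeq2, limma-voom, no filter, a stricter filter (mean count of 10 and more than 1 CPM in 3 libraries), length-scaled TPM counts, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, the replicate number as a block, leaving out mitochondrial, haemoglobin and rRNA genes, protein-coding genes only, each library left out in turn, and transcripts as features. Added after seeing the data were removal of each library's trend over length and GC by a generalised additive model (mgcv), reads recovered from the series table, libraries thinned to equal totals, and leaving out sham 2 with nano-TiO2 3.

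The tests were tested on simulated counts with 200 changed genes. Of genes changed by a log2 of 1 and of 2, edgeR recovered 64% and 98% among 13641 genes, with 14 false calls (7.96% of calls). DESeq2 recovered 79% and 99% with 38 false calls (17.6%) and limma-voom 63% and 98% with 14. With 2 libraries against 2, edgeR recovered 38% and 98%. With a simulated length and GC trend, edgeR made 5673 false calls with the trend left in and 15 with it removed, where 58% and 98% were recovered. That trend was the same in all libraries of a group, and the changed genes were drawn without regard to length. It therefore cannot show whether removal deletes true differences that follow length, or how it handles uneven trends. Limma recovered 8% and 75% of changed bins among 56161. Camera called the 1 changed list (log2 of -0.5) at an adjusted p = 1.38e-50 and 0 others of 39. Simulated genes varied independently, while estimated correlations in the data reached 0.977 (hepatocyte genes). The simulation therefore could not show false list calls from correlated genes.

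R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, mgcv 1.9.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.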

Results

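Fetal hearts were compared between offspring of dams that inhaled an aerosol of titanium dioxide nanoparticles (nano-TiO2, used industrially as a white pigment) and offspring of dams exposed to filtered room air (sham). The mice were FVB/NJ, an inbred strain. Exposure began on gestational day 5 and the hearts were collected on gestational day 15. The target aerosol concentration was 12 mg/m3, given for 360 minutes per day on 6 non-consecutive days within 8 days. The study profiled N6-methyladenosine (m6A), a methyl mark on RNA, by immunoprecipitation. The 6 libraries described here are its input libraries, made from fragmented total RNA with no antibody, so that they measure transcript abundance and not methylation. Each library came from pooled fetal hearts of both sexes, with 3 pools per group. The litters behind each pool are not stated, so p-values measure only the spread between these pools.

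Salmon had assigned 22720009, 17152365 and 22588977 estimated reads to transcripts in sham 1, 2 and 3, and 15197916, 12881945 and 21553478 in nano-TiO2 1, 2 and 3. Haemoglobin transcripts took 12.4%, 23.4% and 10.6% of the reads in sham 1, 2 and 3 and 10.2%, 5.68% and 9.42% in nano-TiO2 1, 2 and 3. The mitochondrially encoded genes took 2.16%, 2.69% and 3.55% in the sham libraries and 2.61%, 1.56% and 2.49% in the nano-TiO2 libraries. The first principal component of log2 CPM (read counts scaled by effective library size) held 45.9% of the variance and put all 3 sham libraries on one side and all 3 nano-TiO2 libraries on the other. The second held 24.4% and spread the libraries within both groups.

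**Figure D1:**
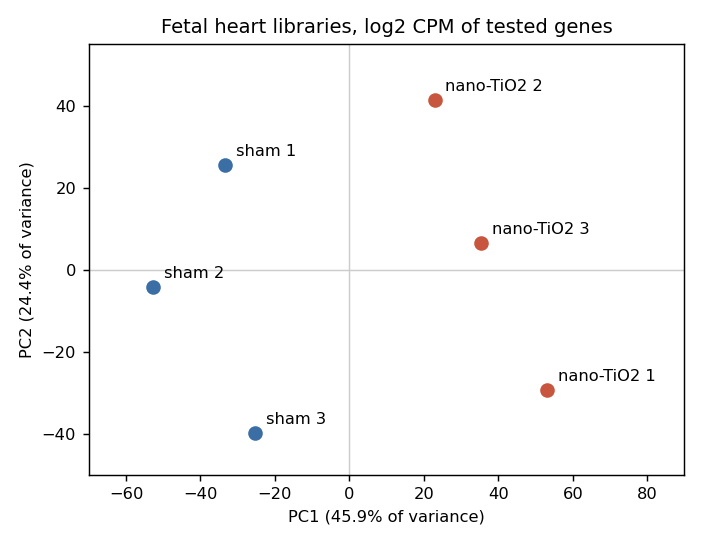
First and second principal components of log2 CPM over the tested genes, one point per library, with sham in blue and nano-TiO2 in red. PC1 (45.9% of variance) separates the groups, while PC2 (24.4%) runs from sham 3 and nano-TiO2 1 at the bottom to nano-TiO2 2 at the top.

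The first comparison asked which genes differed between exposed and sham hearts. The 12 largest rises among well-measured genes with non-overlapping groups were Tmem245, Tmem170b, Magt1, Stard9, Gnai1, Tbl1xr1, Tnks, Zbtb20, Jmy, Sos2, Kcnj3 and Slc16a12, with log2 fold changes from 1.71 (Slc16a12) to 1.93 (Tmem245). Zbtb20, a zinc finger transcription factor, went from 18.2 ± 1.32 CPM in sham to 61.4 ± 20.5 CPM in nano-TiO2 hearts (SD, n = 3 each). Tnks, which encodes the poly-ADP-ribosyltransferase tankyrase, went from 8.41 ± 0.947 to 28.5 ± 6.55 CPM (SD, n = 3 each). Kcnj3, a subunit of the acetylcholine-gated potassium channel of atrial muscle, went from 2.58 ± 0.234 to 8.54 ± 1.84 CPM (SD, n = 3 each). With each library's trend over transcript length and GC removed, these 12 log2 fold changes ranged from 0.49 (Zbtb20) to 1.54 (Magt1), with Tmem245 at 0.74 and Tnks at 0.63, and adjusted p from 0.0551 (Sos2) to 0.285 (Slc16a12). Without nano-TiO2 3 the adjusted p of Magt1 was 0.0564, and without sham 2 that of Slc16a12 was 0.0545.

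Among the 12 largest falls were Klf1, Ints9, Trim10, Slc4a1, Rhd, Tpi1, Apoc1, Hist1h1b, Hbb-bt, Hist1h1e and Hba-a1. Several of these are red-cell genes: Klf1 is the erythroid Krüppel-like transcription factor, Slc4a1 the band 3 anion exchanger and Rhd a blood group protein. Klf1, Slc4a1 and Rhd were highest in sham 2, the library with the most haemoglobin and hepatocyte transcripts, where Klf1 stood at 42.3 CPM against 4.35 in sham 1, 2.44 in sham 3 and 0.486 to 0.875 in the nano-TiO2 libraries. The linker histone gene Hist1h1e fell from 27.7 ± 0.984 to 9.89 ± 0.780 CPM (SD, n = 3 each), a log2 fold change of -1.49 ± 0.15 (SE, adjusted p = 0.0063). Ints9, an Integrator complex subunit, had a log2 fold change of -4.40 in the Salmon estimates and -0.07 in the reads per bin of the series table, and the glycolytic gene Tpi1 had -2.35 and -0.62. Klf1, Trim10, Slc4a1, Rhd, Apoc1, Hbb-bt and Hba-a1 lost their calls without nano-TiO2 1 and without nano-TiO2 3, and all of these except Trim10 without nano-TiO2 2. Klf1, Slc4a1, Rhd, Hbb-bt and Hba-a1 also lost them without sham 1, Apoc1, Hbb-bt and Hba-a1 without sham 2, and Hbb-bt without sham 3. Among these fits the highest adjusted p was 0.194, for Klf1 without nano-TiO2 1.

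In all, edgeR's quasi-likelihood test called 2154 genes higher and 1781 lower among 13930 tested at a Benjamini-Hochberg adjusted p under 0.05. Of the tested genes, 45.7% had non-overlapping groups, against an average of 10% over all splits of the libraries 3 against 3. Genes that vary together are separated by the same split, so this share is not a test over independent genes. Fold change followed transcript length and GC content: the median was -0.45 in the quintile of genes with the shortest transcripts (955 lower, 26 higher) and 0.68 in the quintile with the longest (1203 higher, 50 lower). It was 0.50 in the quintile with the lowest GC (802 higher, 55 lower) and -0.43 in the quintile with the highest (833 lower, 7 higher). Length and GC together accounted for 39.9% of the variance of the fold changes across genes, which are not independent replicates.

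**Figure D2:**
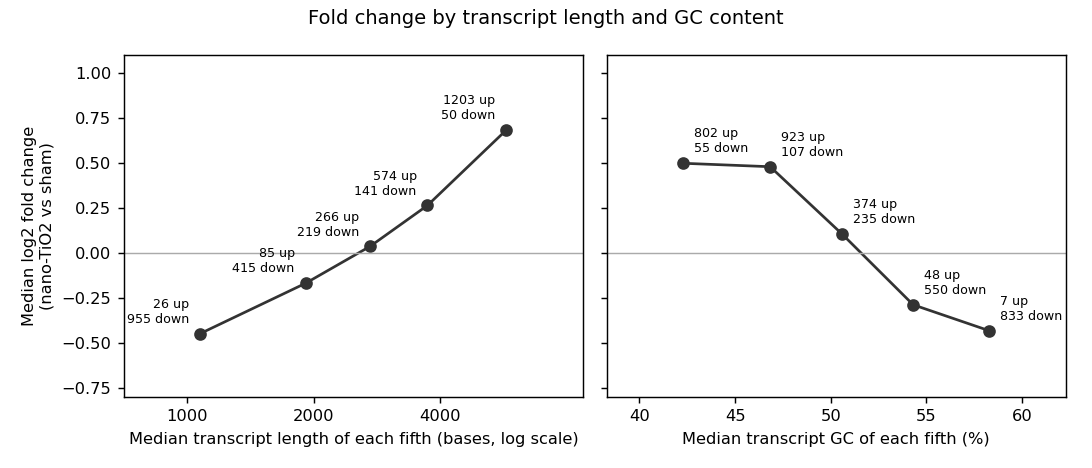
Median log2 fold change (nano-TiO2 against sham) in quintiles of the tested genes by transcript length (left, log axis) and by transcript GC content (right), with the number of genes called higher and lower beside each point. The median runs from -0.45 to 0.68 with length and from 0.50 to -0.43 with GC.

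With each library's trend over length and GC removed, a setting chosen after seeing the data, 17 genes were higher and 66 lower, and 43 calls were shared in the same direction. Of these 83 calls, 32 had a call in the same direction in the reads of the series table, and 31 lay within 0.25 log2 of no change there. The fit to those reads kept the trend, so a gene near no change there can still depart from its trend. These counts therefore do not measure how well the 2 sources match. Of the 78 named genes with a call, 3 (Ints9, Hist1h1e and Hist1h1b) were still called. Leaving out sham 2 and nano-TiO2 3, the libraries richest in liver and lung transcripts, left 0 calls by edgeR and 0 by limma-voom (3350 and 3385 genes at an unadjusted p under 0.05) and 563 higher and 267 lower by DESeq2. Across genes, the fold changes without these 2 libraries correlated with those from all 6 at 0.920, where the 4 shared libraries alone give 0.816 with no effect. By camera 15 of the 16 list calls were kept, from a fit that shares those 4 libraries. Leaving out a single library gave 864 to 2190 genes higher and 425 to 2082 lower, with the lowest number of higher genes without nano-TiO2 1 and the lowest number of lower genes without sham 2. Higher genes were 54.7% of the calls with TMM scaling, 64.9% with upper-quartile scaling and 98.8% with library totals only, which shifted the median gene by 0.41. They were 99.7% on log2(TPM + 1), where the median gene lay at 0.48, so that directions given here are relative to the median gene.

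Transcripts of the m6A machinery were among the genes that differed. Mettl14, which forms the core methyltransferase with Mettl3, rose from 7.35 ± 0.938 to 14.4 ± 2.93 CPM (SD, n = 3 each; log2 fold change 0.96 ± 0.21 SE, adjusted p = 0.0158). Mettl3 itself stood at 15.5 ± 1.46 and 13.4 ± 1.13 CPM (SD, n = 3 each; adjusted p = 0.382). Of 12 writer genes, 6 were higher, 1 was lower and 5 did not pass; adjusted over the list alone, 7 were higher and 1 lower. Mettl16 (0.81) and Zc3h13 (0.64) rose, and Pcif1, which methylates the cap-adjacent adenosine, fell (-0.47). The writer list as a whole did not pass (adjusted p = 0.117). Of the 2 demethylases edgeR called 0, DESeq2 0 and limma-voom 0, with 0 at an unadjusted p under 0.05 by edgeR. Fto had a log2 fold change of -0.27 ± 0.19 (SE, adjusted p = 0.309) and Alkbh5 0.10 ± 0.13 (SE, adjusted p = 0.611). Among 15 readers, 9 were higher and 1 lower, also adjusted over the list alone. Ythdf2, which promotes decay of methylated RNA, rose from 53.1 ± 8.06 to 82.0 ± 5.45 CPM (SD, n = 3 each; log2 fold change 0.63 ± 0.15 SE, adjusted p = 0.0179). Ythdf3 (1.04), Eif3a (1.04) and Igf2bp3 (0.87) rose too. The readers Igf2bp1, Igf2bp2 and Igf2bp3 also served below as genes that fall with gestational age, and a difference in stage between pools was left open. The readers passed the list test with camera's preset correlation (adjusted p = 0.0051) but had an adjusted p = 0.354 with an estimated correlation, and adjusted p = 0.236 with the length and GC trend removed. Their estimated correlation was -0.031, below the preset, so correlation among readers does not account for the first of these losses. With that trend removed edgeR called 0 genes of the 3 m6A lists (5 higher and 4 lower at an unadjusted p under 0.05), the log2 fold change of Mettl14 was 0.49, that of Ythdf2 0.09 and that of Mettl16 -0.15. In that setting Alkbh5 was at -0.54 and Fto at -0.37, and both demethylases passed as lower adjusted over the list alone (2 of 2), though not over all genes (adjusted p = 0.0925 and 0.287). Mettl14 and Ythdf2 lost their calls without sham 2, nano-TiO2 1 or nano-TiO2 3 (adjusted p up to 0.0612 and 0.0702), and Mettl16 without sham 2 or nano-TiO2 1 (up to 0.0583). Pcif1 lost its call without any library except nano-TiO2 2 (up to 0.0934), Zc3h13 without sham 1, sham 2, nano-TiO2 1 or nano-TiO2 3 (up to 0.0906) and Ythdf3 without nano-TiO2 1 (0.0540). The 6 higher writers became 3 without sham 1, 1 without nano-TiO2 3 and 0 by edgeR without sham 2 or without nano-TiO2 1 (6 at an unadjusted p under 0.05 in both fits). With length-scaled TPM counts 3 writers and 4 readers were higher. The 9 higher readers became 4 without sham 2, 2 without nano-TiO2 1 and 3 without nano-TiO2 3. On log2(TPM + 1), where the median gene lay at 0.48, the fold changes of Mettl3, Fto and Pcif1 were above 0, at 0.56, 0.36 and 0.19.

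**Figure D3:**
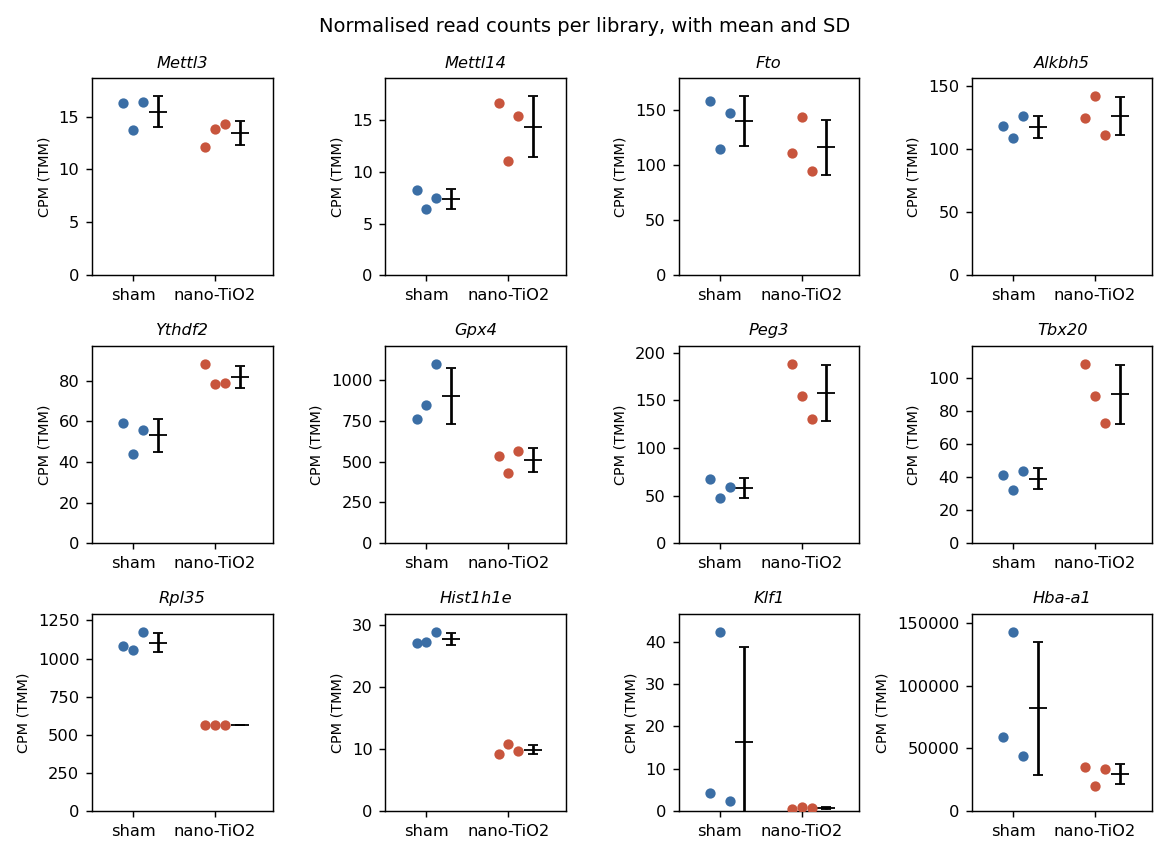
Normalised read counts (CPM, TMM scaling) of 12 genes in each library, with sham in blue, nano-TiO2 in red and the mean with its SD (n = 3) as a bar beside the points; the axes start at 0. Mettl3, Fto and Alkbh5 overlap between groups, Mettl14, Ythdf2, Peg3 and Tbx20 are higher in every nano-TiO2 library, and the sham mean of Klf1 rests on sham 2, with an SD larger than that mean, drawn down to 0.

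Most genes of the cytosolic ribosome and 5 of 11 tested histone genes were lower relative to the median gene. Of 67 cytosolic ribosomal protein genes, 62 fell and none rose (63 adjusted over the list alone), with a median log2 fold change of -0.72. Rpl35 fell from 1104 ± 62.1 to 563.4 ± 1.50 CPM (SD, n = 3 each; log2 fold change -0.97 ± 0.11 SE, adjusted p = 0.0063), and Rps27 (-0.94) and Rps15a (-0.93) fell likewise. The median of the ribosomal protein genes stayed below 0 under every scaling tried, at -0.30 with library totals only and -0.06 on log2(TPM + 1), and was -0.25 with the length and GC trend removed. The 62 lower calls became 40 without sham 2, 39 without nano-TiO2 1, 9 with library totals only and 1 with the trend removed, and on log2(TPM + 1), where the median gene lay at 0.48, 2 genes were called, both higher. The list passed the preset-correlation test (adjusted p = 7.25e-30) but had an adjusted p = 0.261 with an estimated correlation. Of these replication-dependent histone genes, 5 fell (5 adjusted over the list alone; median -0.69), among them Hist1h4d (-1.90), Hist1h1b (-1.60) and Hist1h2ae (-1.29). This list had an adjusted p = 3.31e-05, and an adjusted p = 0.296 with an estimated correlation. The histone median was -0.32 with library totals only and -0.10 on log2(TPM + 1), where 3 genes were lower and 1 higher. With the length and GC trend removed it was -0.20, and Hist1h1e and Hist1h1b were still called, at -1.43 and -1.10. Ribosomal protein, histone and globin genes have near-identical copies or pseudogenes, so the split of reads among them is uncertain.

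Among genes of energy metabolism, the lists of nuclear-encoded respiratory chain, mitochondrially encoded, mitochondrial ribosome and glycolysis genes pointed down relative to the median gene in the preset-correlation test. Over all lists, that test called 16 in the real grouping and 3 to 19 in splits of the libraries that mixed the groups. In nuclear-encoded complex I of the respiratory chain, 24 of 36 genes fell (32 adjusted over the list alone; median -0.65), with Ndufb2 at -0.80 and Ndufa3 at -0.80. In complexes II to V, 25 of 42 fell (28 adjusted over the list alone; median -0.65), with Cox7a2 at -0.88 and Atp5k at -0.83. These 2 lists had adjusted p = 2.87e-10 and 3.57e-10, and both an adjusted p = 0.665 with an estimated correlation. Their estimated correlations were 0.871 and 0.867, far above the preset 0.01, so the preset test overstates the evidence for them. By fry they had adjusted p = 0.104 and 0.120. On log2(TPM + 1) their medians were 0.02 and -0.01, against 0.48 for the median gene. With library totals only, 1 gene of complex I was called, higher, and 2 of complexes II to V, 1 higher and 1 lower, and on log2(TPM + 1) 1 and 3 genes were called, all higher. Their medians were -0.17 and -0.19 with the length and GC trend removed, with 0 genes of complex I (2 at an unadjusted p under 0.05 by edgeR) and 1 of complexes II to V called. The 24 lower genes of complex I became 10 without sham 2, 10 without sham 3, 11 without nano-TiO2 1, 14 without nano-TiO2 2 and 8 without nano-TiO2 3. The 25 of complexes II to V became 11 without sham 2, 14 without sham 3, 13 without nano-TiO2 1 and 13 without nano-TiO2 3. Of 13 mitochondrially encoded proteins, 2 fell (1 adjusted over the list alone; median -0.72): mt-Co3, from 6375 ± 1013 to 3628 ± 821 CPM (SD, n = 3 each), and mt-Atp8 (-0.80). Without nano-TiO2 3 the adjusted p of mt-Co3 was 0.0623, and mt-Atp8 lost its call in all fits without 1 library except that without sham 1 (adjusted p up to 0.101). Their list had an adjusted p = 0.00178, and an adjusted p = 0.665 with an estimated correlation, which was 0.815. By fry it had an adjusted p = 0.194. Of 36 genes of the mitochondrial ribosome and biogenesis, 14 fell and 2 rose (17 and 3 adjusted over the list alone), including Mrpl2 at -0.68 and Mrps11 at -0.67. Their list had an adjusted p = 0.00194, an adjusted p = 0.665 with an estimated correlation, and a median that flipped from -0.34 to 0.08 with library totals only and 0.29 on log2(TPM + 1). With library totals only, 5 genes of this list were called, all higher. That list no longer passed with the length and GC trend removed (adjusted p = 0.0892, median -0.12), and its 14 lower genes became 3 without nano-TiO2 1 and 5 to 8 without sham 1, 2 or 3 or nano-TiO2 3. Of 21 glycolysis genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone). Gapdh fell from 2270 ± 81.5 to 1344 ± 109 CPM (SD, n = 3 each) and Aldoa from 5449 ± 63.6 to 3411 ± 108 CPM (SD, n = 3 each). The glycolysis list had an adjusted p = 1.98e-04, an adjusted p = 0.481 with an estimated correlation, and a median that flipped from -0.52 to 0.13 on log2(TPM + 1). With library totals only, 2 glycolysis genes were called higher and 1 lower. The median of the glycolysis list was -0.25 with the length and GC trend removed, with 0 genes called (6 lower at an unadjusted p under 0.05 by edgeR), and the 10 lower genes became 3 without nano-TiO2 1 and 4 to 6 without sham 1, 2 or 3 or nano-TiO2 3. With the length and GC trend removed, mitochondrial dynamics had an adjusted p = 0.0486, pointing down, and an adjusted p = 0.819 with an estimated correlation. Fatty acid oxidation (1 higher, 4 lower of 26) and mitochondrial dynamics, mitophagy and import (4 higher, 10 lower of 32) did not pass as lists with the trend left in, and with library totals only they had 8 and 10 genes called, all higher (medians 0.29 and 0.26), and on log2(TPM + 1) 11 and 12, all higher (0.53 and 0.50).

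Relative to the median gene, more antioxidant genes passed as lower than as higher. Of 39 antioxidant and NRF2 target genes, 16 fell and 2 rose (23 and 3 adjusted over the list alone). Gpx4, which reduces lipid peroxides, fell from 903.9 ± 174 to 511.8 ± 72.8 CPM (SD, n = 3 each; log2 fold change -0.82 ± 0.17 SE, adjusted p = 0.0132), and the peroxiredoxin Prdx2 fell by 0.82 on the log2 scale. Nfe2l2, which encodes the regulator NRF2, rose (0.77 ± 0.15 SE, adjusted p = 0.0117). Without sham 2 the adjusted p of Gstp1 (-0.63) was 0.0542, and Prdx4 (-0.60) lost its call without sham 1 or nano-TiO2 1 (up to 0.0622). The list had an adjusted p = 1.33e-04, an adjusted p = 0.477 with an estimated correlation, and a median that flipped from -0.48 to 0.18 on log2(TPM + 1), where the median gene lay at 0.48. With library totals only 4 genes were called and on log2(TPM + 1) 5, all higher. The median was -0.14 with the length and GC trend removed, where 1 gene was lower, and the 16 lower genes became 5 without sham 1, 4 without sham 2, 5 without nano-TiO2 1 and 5 without nano-TiO2 3. None of the other stress or immune lists passed: xenobiotic response had 4 genes higher and 1 lower of 7, hypoxia 4 and 2 of 22, p53 targets 2 and 2 of 20, the unfolded protein response 3 and 2 of 27, heat shock 2 and 3 of 14, immediate early genes 2 and 1 of 21, and inflammation 1 and 2 of 17. Under library totals only, p53 targets had 5 genes called, the unfolded protein response 4, heat shock 4 and immediate early genes 4, all higher. The xenobiotic calls became 0 by edgeR without sham 1, sham 2, nano-TiO2 1 or nano-TiO2 3 (5, 4, 3 and 4 higher at an unadjusted p under 0.05). The hypoxia calls became 11, all higher, with library totals only, 14, all higher, on log2(TPM + 1), and 2, both lower, with length-scaled TPM counts; the 4 higher genes became 2 without sham 2 and 1 without nano-TiO2 1. Among 19 interferon-stimulated genes, edgeR called 0, DESeq2 0 and limma-voom 0, with 1 gene at an unadjusted p under 0.05 by edgeR. Cell cycle genes had 3 higher and 8 lower of 42, with an adjusted p = 0.253 for the list. These calls were 7 higher and 4 lower with upper-quartile scaling, 9 and 4 in the reads of the series table and 13, all higher, with library totals only. The 8 lower genes became 1 without sham 1, sham 2, nano-TiO2 1 or nano-TiO2 3. With the length and GC trend removed, the cell cycle list had an adjusted p = 5.53e-08, pointing down with a median of -0.34 and 0 genes called (23 lower at an unadjusted p under 0.05), and an adjusted p = 0.478 with an estimated correlation.

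Sarcomere genes and cardiac transcription factors were tested as separate lists, and the difference between the lists was not tested. Of 29 sarcomere genes, 13 fell and 1 rose (13 and 2 adjusted over the list alone), among them desmin (Des, -0.64), Myl4 (-0.61), Mybpc3 (-0.56) and Actn2 (-0.55). Actn2, Mybpc3 and Myl4 lost their calls without nano-TiO2 1 or nano-TiO2 3, Actn2 and Mybpc3 without sham 1, and Actn2 and Myl4 without sham 2, with adjusted p up to 0.0600, 0.0737 and 0.0570. This list had an adjusted p = 0.00148, an adjusted p = 0.665 with an estimated correlation and an adjusted p = 0.269 with the length and GC trend removed, and its median flipped from -0.49 to 0.19 on log2(TPM + 1), where the median gene lay at 0.48 and Des, Myl4, Mybpc3 and Actn2 also lay above 0. With library totals only 3 sarcomere genes were called and on log2(TPM + 1) 7, all higher. The 13 lower sarcomere genes became 6 without sham 1, 3 without sham 2, 1 without nano-TiO2 1 and 3 without nano-TiO2 3. Of 29 cardiac transcription factors, 10 rose and 1 fell, also adjusted over the list alone. Tbx20 rose from 39.0 ± 6.22 to 90.2 ± 17.8 CPM (SD, n = 3 each; log2 fold change 1.21 ± 0.19 SE, adjusted p = 0.00736), Foxp1 (1.05) and Prox1 (0.91) rose, and Nkx2-5, a core factor of heart formation, fell (-0.66 ± 0.11 SE, adjusted p = 0.00846; 0.066 on log2(TPM + 1)). With the length and GC trend removed, edgeR called 0 of the factors (5 higher at an unadjusted p under 0.05), with Tbx20 at 0.16, Foxp1 at 0.19, Nkx2-5 at -0.32 and Prox1 at -0.18. The list had an adjusted p = 0.0336, an adjusted p = 0.481 with an estimated correlation, 0.140 without sham 3 and 0.0697 without nano-TiO2 2. Calcium handling and conduction (5 higher, 1 lower of 25) and hypertrophy genes (3 higher of 15) did not pass as lists. Under library totals only they had 10 and 5 genes called, all higher.

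More chromatin and imprinted genes passed as higher than as lower. Of 30 DNA methylation and chromatin modifiers, 12 rose and 1 fell (14 and 2 adjusted over the list alone). The DNA demethylase gene Tet2 rose from 5.90 ± 1.57 to 17.1 ± 2.66 CPM (SD, n = 3 each), and Kmt2a (1.08), Crebbp (1.07) and Suz12 (1.00) rose. The 12 higher modifiers became 4 with length-scaled TPM counts and 0 by edgeR with the length and GC trend removed (5 higher and 4 lower at an unadjusted p under 0.05), where Tet2 was at 0.43, Crebbp at 0.37, Suz12 at 0.29, Kmt2a at 0.10 and the median went from 0.48 to 0.11. Of 20 imprinted growth and IGF signalling genes, 5 rose and 1 fell, also adjusted over the list alone. Peg3 rose from 57.9 ± 10.2 to 157.5 ± 29.1 CPM (SD, n = 3 each), and Zim1 (1.35), Plagl1 (1.16) and Igf1r (0.83) rose. The 5 higher imprinted genes became 3 without nano-TiO2 1. The adjusted p of Zim1 was 0.0641 without nano-TiO2 1, and with the length and GC trend removed Peg3 was at 0.34, Plagl1 at 0.30, Zim1 at 0.29 and Igf1r at -0.13. The 2 lists had adjusted p = 0.0149 and 0.0374, and adjusted p = 0.481 and 0.665 with an estimated correlation. Neither passed without sham 3 (adjusted p = 0.0701 and 0.20), without nano-TiO2 2 (0.0844 and 0.183) or with the length and GC trend removed (0.262 and 0.688).

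**Figure D4:**
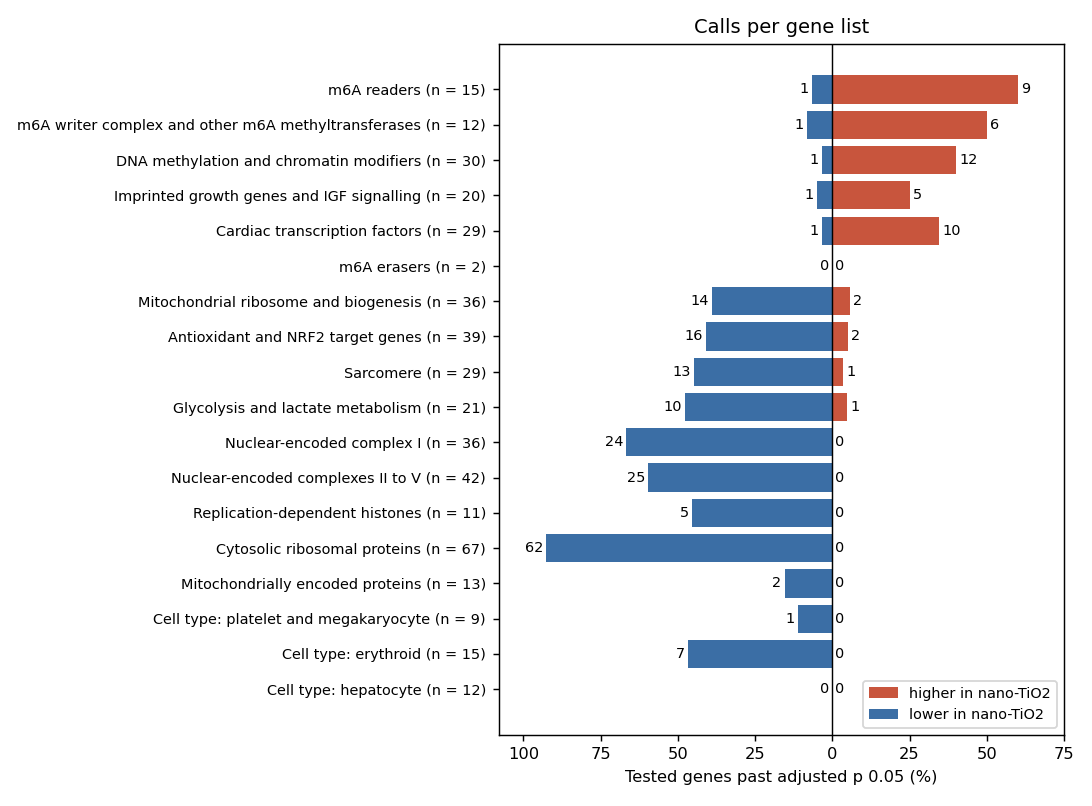
Share of each list's tested genes called higher (red, right) and lower (blue, left) in nano-TiO2 hearts, with the number of genes beside each bar, for the m6A lists and the lists past the preset-correlation test. Lists are ordered by median log2 fold change. Ribosomal protein genes (62 of 67) have the largest share lower and m6A readers (9 of 15) the largest share higher. No list passed with an estimated correlation.

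Markers of other cell types showed what else the pools held. Of 15 erythroid genes, 7 fell and none rose (8 adjusted over the list alone; median -1.22), with Hba-a1 at -1.47 and Fech, the last enzyme of haem synthesis, at -0.93. Fech lost its call without any 1 of 5 libraries (all but sham 3; adjusted p up to 0.123). The list had an adjusted p = 0.00178, and an adjusted p = 0.665 with an estimated correlation. Without sham 2 its median was -0.78 and 2 of the 15 genes, Klf1 and Slc4a1, passed; edgeR called 0 without sham 1, nano-TiO2 1, nano-TiO2 2 or nano-TiO2 3 (10, 8, 9 and 8 lower at an unadjusted p under 0.05). The 7 lower genes became 2 with limma-voom, 3 with upper-quartile scaling, 3 with length-scaled TPM counts, and 0 by edgeR with library totals only, with no low-count filter and with the length and GC trend removed (5, 5 and 7 lower at an unadjusted p under 0.05). Hepatocyte genes were concentrated in sham 2, where Alb reached 156 CPM against 1.09 to 18.8 CPM elsewhere. Of 12 hepatocyte genes edgeR called 0 (7 lower at an unadjusted p under 0.05) and DESeq2 8 lower, while the list passed (adjusted p = 0.0105; adjusted p = 0.706 with an estimated correlation). Lung epithelial genes were concentrated in nano-TiO2 3. Sftpc, the surfactant protein C gene, stood at 1389 CPM there, 259 in nano-TiO2 2, 129.6 in sham 1 and 0.304 to 19.4 in the other libraries. Of 11 lung genes edgeR called 0 (2 higher at an unadjusted p under 0.05) and DESeq2 0, and the list had an adjusted p = 0.489. Of 9 platelet genes, 1 (Gp9, -1.39) fell, and 5 fell adjusted over the list alone. That list had an adjusted p = 0.0199, an adjusted p = 0.665 with an estimated correlation, an adjusted p = 0.0509 without sham 2, 0.0791 without nano-TiO2 3 and 0.0815 with the length and GC trend removed (median -0.39 against -0.93); Gp9 itself lost its call without sham 2, nano-TiO2 1 or nano-TiO2 3 (adjusted p up to 0.0570). Other cell type lists did not pass: fibroblast and matrix had 4 higher and 2 lower of 26, endothelial 4 and 3 of 23, epicardial 3 and 0 of 15 (adjusted p = 0.0302, pointing up, with the length and GC trend removed, and an adjusted p = 0.478 with an estimated correlation), smooth muscle 1 and 3 of 14, macrophage and other leukocytes 1 and 0 of 15, neural 2 and 0 of 9, skeletal muscle 0 and 0 of 12 and sex-linked genes 0 and 0 of 4. These 2 lists had 1 and 0 genes at an unadjusted p under 0.05 by edgeR, 1 and 0 calls by DESeq2 and 0 and 0 by limma-voom. The 4 sex-linked genes matched, of 6 listed, summed to 6.14, 31.05 and 43.82 CPM in sham 1, 2 and 3. They summed to 26.6, 18.75 and 33.99 in nano-TiO2 1, 2 and 3, so the pools differed in sex-linked transcripts. The epicardial calls were lost by edgeR without nano-TiO2 1, and the neural calls without sham 2 or nano-TiO2 3 (3, 2 and 2 higher at an unadjusted p under 0.05). Median, mean and test differed in sign for 9 lists, with adjusted p from 0.532 to 0.831: fatty acid oxidation, p53 targets, immediate early, interferon-stimulated, endothelial and macrophage genes (median below 0, mean above 0, test down), inflammation (median above 0, mean below 0, test down), skeletal muscle (median and mean above 0, test down) and sex-linked genes (median below 0, mean above 0, test up).

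The second comparison used the table of the whole series, which gives scaled reads in bins along each gene. Among 245114 bins with a mean of at least 10, limma on log2(value + 1) called 2790 higher and 10987 lower, with a median bin at -0.25 under the authors' scaling. The higher bins lay in 375 genes and the lower bins in 1939, and no gene had both. Of 1630 genes called lower from the Salmon estimates and covered by a tested bin, 1056 had a lower bin and none a higher one. Of 551 called higher and covered, 255 had a higher bin and 5 a lower one. Rescaling the bins by TMM factors gave 3938 higher and 590 lower, and leaving out sham 1, sham 2, nano-TiO2 1 or nano-TiO2 3 left at most 19 higher and 59 lower bins, with 0 of either without nano-TiO2 1 (45221 bins at an unadjusted p under 0.05 by limma).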

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

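The tests of GC preference, coverage toward the 3' end and short-molecule loss were chosen only after the result was seen, as was the look at transcript classes in the series table; the test of retained introns was set before its result was seen. The rule for coverage was changed after its value was known, so that it had to give the same answer without each library in turn.

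In the series table, 2065 tested genes had no matched transcript in the per-sample files, and 296 of them were higher and 82 lower in nano-TiO2 hearts, a signal outside the main measurement. Over all 18850 genes tested there, 2900 were higher, so the share among the unmatched genes was no larger. Of 488 genes of the annotation class TEC, unspliced transcripts awaiting experimental evidence, 154 were higher and 10 lower there. Their median lay 0.55 log2 above a length and GC trend, with an SD over genes of 0.92. That trend was fitted to the protein-coding genes of the series table and carried over to the other classes, for which it may not hold. Sense-intronic genes had 16 higher of 49, at a median of 0.58 above the trend (SD over genes 1.20), lincRNAs 38 higher and 10 lower of 315, at 0.16 (0.67), and processed pseudogenes 32 higher and 636 lower of 2530, at -0.08 (0.42).

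Fold changes followed length and GC, at 0.30 log2 per doubling of transcript length. The tables argue against GC preference of the sequenced fragments as a cause of this size. Between low-GC and high-GC bins the groups differed by 0.0793 ± 0.00965 log2 (SE over genes) across whole transcripts. Within tertiles along the transcripts they differed by 0.0284 ± 0.00683 log2, where 0.372 was needed. This SE is over 1475 tertiles, and those of the same gene are not independent. Every nano-TiO2 library lay above every sham library in this value (-0.4565 to -0.4451 against -0.488 to -0.4691), so a small preference is not excluded. The values also argue against loss of short molecules, since the slope was 0.341 ± 0.00879 (SE over genes) among genes of at least 2000 bases. A larger share of nuclear or unspliced RNA in nano-TiO2 libraries is a candidate explanation: within 2291 genes, reads on retained-intron against protein-coding transcripts were higher by a median of 0.408 log2 ± 0.0297 (SE over genes), with every nano-TiO2 library above every sham library, though Salmon divides reads among overlapping transcripts and these differ in length and GC. Coverage shifted to the 3' end stays open too, since the read share there differed by 0.682 percentage points and the groups overlapped only through sham 2 (27.2% against 24.4% and 23.9% in the other sham and 24.7% to 28.0% in the nano-TiO2 libraries), as does whether these patterns come from RNA preparation or from the exposure itself.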

How the results depend on the processing

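Removal of the length and GC trend, reads from the series table, thinning, leaving out sham 2 with nano-TiO2 3, and every alternative of the series table were chosen only after the result was seen.

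The 2154 higher and 1781 lower genes stayed within 1.5 times those counts in both directions with RLE or upper-quartile factors, DESeq2, limma-voom, both other filters, protein-coding genes only, removal of mitochondrial, haemoglobin and rRNA genes, reads from the series table and thinning. They did not with library totals only (4270 and 50), log2(TPM + 1) (4532 and 16) and log2(TPM + 0.1) (4489 and 15), which use no composition factors and put the median gene at 0.41, 0.48 and 0.56, or with length-scaled TPM counts (1390 and 1042) and transcripts as features (280 and 334), where the cause was not tested. Removal of the length and GC trend gave 17 and 66 (2320 genes at an unadjusted p under 0.05), and 432 of the original calls changed sign. Leaving out 1 library gave 864 to 2190 higher and 425 to 2082 lower. Fewer genes by over 1.5 times were called higher without sham 2 (1028), nano-TiO2 1 (864) or nano-TiO2 3 (1028), and lower without sham 1 (552), sham 2 (425), sham 3 (1132), nano-TiO2 1 (439) or nano-TiO2 3 (541). Without sham 2 and nano-TiO2 3 edgeR called 0 and 0 (3350 at an unadjusted p under 0.05), limma-voom 0 and 0 (3385), and DESeq2 563 and 267, while the fold changes correlated with those from all 6 libraries at 0.920 across genes, against 0.816 with no effect because 4 libraries are shared, and 15 of the 16 lists stayed called from those 4 libraries.

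Of 16 lists past camera, 0 passed with an estimated correlation (smallest adjusted p = 0.261), and 0 lists did with the trend also removed. The estimate was -0.031 for readers, 0.010 for cardiac transcription factors and 0.977 for hepatocyte genes. Losses at values near the preset 0.01 do not come from correlated genes, since that setting also has few degrees of freedom. With the trend removed and the preset correlation 13 lists passed, 10 of them among the 16; the other 3 were cell cycle, mitochondrial dynamics and epicardial genes. Fry called 7. Leaving out 1 library gave 13 to 19 lists. In the series table, a minimum mean of 50 gave 1176 higher and 17763 lower bins, TMM factors 3938 and 590, and leaving out sham 2 with nano-TiO2 3 gave 1 and 0 (39824 at an unadjusted p under 0.05 by limma). Leaving out 1 library gave 0 to 3116 higher and 0 to 10682 lower bins: 19 and 52 without sham 1, 3 and 2 without sham 2, 0 and 0 without nano-TiO2 1 (45221 at an unadjusted p under 0.05) and 2 and 59 without nano-TiO2 3.

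With the replicate number as a block, 1262 genes were higher and 795 lower, and 2075 bins higher and 7400 lower. The numbers do not pair the libraries: same-numbered deviations correlated at -0.390, 0.0218 and -0.0812, and no library correlated best with its own number.

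Named genes kept direction and side of the threshold in 1643 comparisons with an alternative, fell short of it in 365, newly passed in 17 and reversed in 37. Reversals on log2(TPM + 1) and log2(TPM + 0.1) were Actn2 0.21 and 0.21, Cox8a 0.081 and 0.081, Des 0.033 and 0.033, Fto 0.36 and 0.37, Gpi1 0.10 and 0.10, Gstp1 0.044 and 0.044, Mettl3 0.56 and 0.62, Mrpl2 0.0019 and 0.0018, Mrpl4 0.15 and 0.15, Mrps11 0.020 and 0.020, Mybpc3 0.11 and 0.11, Myl4 0.052 and 0.052, Nkx2-5 0.066 and 0.067, Pcif1 0.19 and 0.19, and Prdx4 0.059 and 0.060, against a median gene of 0.48 and 0.56. With library totals only, Fto (0.15) and Mettl3 (0.21) reversed. With the length and GC trend removed, Alkbh5 (-0.54), Igf1r (-0.13), Mettl16 (-0.15), mt-Atp8 (0.095) and Prox1 (-0.18) reversed. List calls were kept in 183 comparisons and lost in 57, with 0 reversals. Depth was not shown to limit the counts, since thinning to equal totals gave 2103 higher and 1638 lower.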

Other observations

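The erythroid tests and the nuclear RNAs were chosen only after the result was seen, as were the values of Ints9 and the order of the globins within groups; the globin stage test and the splits of the libraries were set before their results were seen.

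In the gene-level reads of the series table, 8 long noncoding RNAs picked by hand were each called higher in nano-TiO2 hearts, with no test of them as a group; of 315 lincRNAs tested there, 38 were higher and 10 lower. Neat1, the scaffold of paraspeckles, was at 1.84 ± 0.30 log2 (SE, n = 3 each, adjusted p = 0.00568 by edgeR), Malat1 at 1.32 ± 0.26 (adjusted p = 0.00859 by edgeR), and the imprinted Meg3 at 1.58 ± 0.20 (adjusted p = 0.00388 by edgeR). Firre (1.61), Xist (1.60), Tug1 (1.35), Airn (0.97) and Kcnq1ot1 (0.62) lay in the same direction. Xist is sex-linked, so its value also depends on the sexes in each pool. These 8 stood above the length and GC trend of the protein-coding genes in the series table by 0.12 (Kcnq1ot1) to 1.65 (Meg3). That trend was not fitted to noncoding genes and may not hold for them.

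Erythroid genes were lower in nano-TiO2 hearts, with a median of -1.22. Liver RNA in sham 2 is not the whole cause by the bound used, since without that library the median was -0.784 ± 0.0829 (SE over genes), although 2 of 15 genes were then called. Erythroid genes vary together (estimated correlation 0.576), so that SE does not measure the spread between pools. Sham 3 also held more Alb (18.8 CPM) than the nano-TiO2 libraries (1.09 to 9.60), so its liver RNA was not removed. A different share of blood in the dissected hearts stays open: 0 of 13 genes of at least 5 CPM departed from the adult haemoglobin fold of -0.82 by over 1 log2 beyond 2 standard errors, but Klf1 (-2.28 ± 0.47 SE), Slc4a1 (-1.50 ± 0.29 SE) and Slc25a37 (0.18 ± 0.32 SE) lay more than 0.5 from it, where a blood share as the only cause needed all within 0.5. Sham 2 held 204 CPM of Afp and 224 CPM of Apoa1, against 0.365 to 15.5 and 0.851 to 15.1 elsewhere.

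Embryonic alpha-globin Hba-x differed within groups, at 913, 600.3 and 40.2 CPM in the sham libraries and 30.5, 674 and 24.4 in the nano-TiO2 libraries. Pools of different developmental stage are a possible explanation. Over the 6 libraries, the ratio of Hba-x to Hba-a1 and the mean of 6 genes that fall with gestational age had a Spearman rho of 0.143 (exact permutation p = 0.803) and a Pearson r of 0.578 (exact permutation p = 0.222), which was -0.30 without the 2 farthest libraries; 1 relation was computed. The rho lay below the bound of 0.5 set beforehand as speaking against this explanation. Its 95% upper limit, added as a criterion after the value was seen, was 0.855. The rho also pooled the groups, although the mean of these genes differed between them. That mean was 4.28 to 5.074 log2 CPM in the nano-TiO2 libraries and 3.919 to 4.198 in the sham libraries. Igf2bp1, Igf2bp2 and Igf2bp3 among these genes are also m6A readers, so the mean and the reader list are not separate measurements. Within each group the ratio and the mean ranked the libraries alike, from the highest down: sham 1, 2, 3 and nano-TiO2 2, 1, 3. This order was seen afterwards and was not tested, so 6 libraries leave the explanation open.

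Ints9 illustrates reads assigned to transcripts: 1 transcript held 526, 285 and 453 estimated reads in sham 1, 2 and 3 and 0 in all 3 nano-TiO2 libraries, while another held 9.05 to 18.6 in the 6 libraries, and in the series table the gene stood at -0.07 (adjusted p = 0.80 by edgeR). Of 13774 genes tested in both sources, 516 called from the estimates lay within 0.5 log2 of no change in the table and were not called there, and 18 called genes differed by over 1 log2.

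The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 3935 genes and the highest other 3, with 1 split as large as the real one, itself. With the length and GC trend removed the values were 83 and 18 (1 split as large), and for bins they were 13777 and 108 (1 split as large). Each other split mixes the groups, so any difference between sham and nano-TiO2 libraries widens its spread and lowers its calls. The low gene and bin counts of the other splits therefore do not measure what chance alone gives. For lists past camera the real split gave 16 and the highest other 19, and 4 splits gave as many, the real one included. The number of lists past camera therefore does not set the real split apart.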
